A study of Homo sapiens with 6 samples.

How the data were processed

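RNA was measured in 6 libraries of an established human bladder cancer cell line. Per the series description, the cells of all 6 libraries had received dCas13b-FTO, a catalytically dead RNA-guided Cas13b fused to FTO, an enzyme that removes N6-methyladenosine (m6A) from RNA. The labels put 3 libraries in a group with a control guide RNA and 3 in a group with a guide against HRAS, sequenced 48 h after transfection. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which can be technical only.

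The deposited values are whole-number counts per gene, not normalized, in a single table of 60664 rows with Ensembl gene identifiers and a column per library. A row with no values (1 row) was left out, and 60663 rows were used. Columns were matched to libraries by the guide and the replicate number in their names. The names disagree on the construct: the columns name FTO, and the sample titles dCas13b without FTO. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the hg38 build, without versions or roles. The tool that made the counts, the annotation release behind them and the strandedness of the libraries are not given in the sources used here. Reads from genes that overlap on opposite strands, and from near-identical copies such as keratin pseudogenes, therefore cannot be assigned with certainty. Gene symbols came from a table of gene names, which held 60462 of the identifiers. Coordinates, transcript lengths and GC content came from GENCODE release 29 on GRCh38, the same assembly as hg38, with the median over a gene's transcripts.

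Library totals ran from 24968702 to 32283370 counts. Genes were filtered with filterByExpr, which left 19836 genes, and scaled by TMM factors. The groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are HRAS guide minus control guide, ± the standard error (SE) recovered from the F statistic. CPM, counts scaled to a common TMM-adjusted library size, are given as mean ± SD. Confidence intervals are at 95%, from the same SE.

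Before the data were examined, the groups, this test, 28 gene lists, the rule for naming genes and a set of alternatives were fixed. The lists are MAPK output, immediate early, RAS signalling components, m6A machinery, interferon response, NF-kB and cytokines, G1/S and DNA replication, G2/M and mitosis, p53 targets and apoptosis, ER stress and integrated stress, heat shock, mesenchymal and invasion, luminal urothelial, basal and squamous, YAP/TEAD targets, glycolysis and hypoxia, cholesterol synthesis, FOXO targets, cytosolic ribosomal proteins, nuclear OXPHOS subunits, mitochondrial genome mRNAs, replication-dependent histones, nuclear-retained and structured RNAs, HRAS chromosomal neighbours, and markers of immune cells, fibroblasts and muscle, endothelium and red cells, and HEK293 and neural cells. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists, and also with an estimated correlation and with fry. A list needed 3 tested members, which left out 1 list.

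Genes were named by a fixed rule. HRAS, FTO and NRAS are given whatever their values. Genes past the threshold with a mean of at least 5 CPM and non-overlapping groups are named, up to 12 in each direction. Each list contributes up to 4 members past the threshold or, with none, the 2 of smallest p, given as values. With fewer than 10 genes past the threshold, the 10 of smallest p are named too. Some genes that the rule selects are not reported here.

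Alternatives fixed beforehand were DESeq2 (1.42.0), limma-voom, a test against a fold of 1.2 (glmTreat), DESeq2 size factors or library totals alone in edgeR, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, fold thresholds, and each library left out in turn. Alternatives added after seeing the data were a correction for GC content and length, and a covariate for sets of libraries that share the sign of their GC trend. The correction fits each library's log2 CPM (prior count 2), relative to the mean of all libraries, to splines of GC content and log10 transcript length (5 and 4 degrees of freedom, robust regression, genes with a mean log2 CPM above 1). The fitted values enter edgeR as offsets, for 19489 genes with annotation.

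The scripts were tested on simulated data in which a set of genes of this comparison was changed by known folds. Without a GC trend, over 19443 genes, the test called 0% of genes changed 1.25-fold, 54% of those changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 4-fold, with 9 unchanged genes called. With simulated GC trends, over 19434 genes, it called 12% of genes changed 1.5-fold and 70% of those changed 2-fold, with 0 unchanged genes called. The correction, over 19103 genes, raised these to 78% and 89.8%, with 11 unchanged genes called. The simulated trends were straight lines, and genes varied independently around them. The simulation with trends used the gene dispersions of the corrected fit (common dispersion 0.0052), and that without a trend those of the uncorrected fit (0.0142). The libraries held no other simulated structure, so these rates need not hold for the real data.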

Results

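RNA levels were measured by RNA sequencing in an established human bladder cancer line, to see how gene expression differs when an m6A demethylase is steered to HRAS transcripts. Per the series description all cells received the dCas13b-FTO fusion, while the sample titles name dCas13b alone. The control group of 3 libraries received a control guide, and the other 3 libraries a guide against HRAS, which encodes a small GTPase of the RAS-MAPK pathway. The control libraries held 28657817, 28374402 and 30502171 counts, and the HRAS guide libraries 24968702, 28816414 and 32283370. Mitochondrial mRNAs took 5.42% to 5.87% of counts and the 10 most abundant genes 6.64% to 7.13%. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom between pairs ran from 3.04 to 39.2, and was highest between control replicates 1 and 2.

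HRAS mRNA (ENSG00000174775, GRCh38 chromosome 11, 532242 to 537287, minus strand) did not differ detectably between the guides. It stood at 146, 230 and 169 CPM in control replicates 1 to 3 and at 200, 167 and 184 CPM in HRAS guide replicates 1 to 3. The means were 182 ± 43.7 CPM (SD, n = 3) and 184 ± 16.5 CPM (SD, n = 3). The log2 fold change was 0.01 ± 0.15 (SE), with a 95% interval of -0.32 to 0.35 and an adjusted p of 1.00 by edgeR. Leaving out control replicate 1 gave -0.13 and leaving out control replicate 2 gave 0.22, both short of the threshold. Without control replicate 3 or HRAS guide replicate 1 it was also below 0, at -0.05 each. The related gene NRAS (-0.09 ± 0.14) also did not pass. FTO, the demethylase gene whose fusion was transfected in both groups, stood at 35.4 ± 3.03 CPM with the control guide and 31.2 ± 0.24 CPM with the HRAS guide (SD, n = 3). Its log2 fold change of -0.19 ± 0.10 did not pass, and reads from the fusion, if counted, cannot be told from the cell's own FTO here. After the GC and length correction FTO stood at -0.20 ± 0.06, with a 95% interval of -0.336 to -0.055. It did not pass there either (edgeR adjusted p = 0.653), but equal FTO RNA in the groups was not shown.

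**Figure D1:**
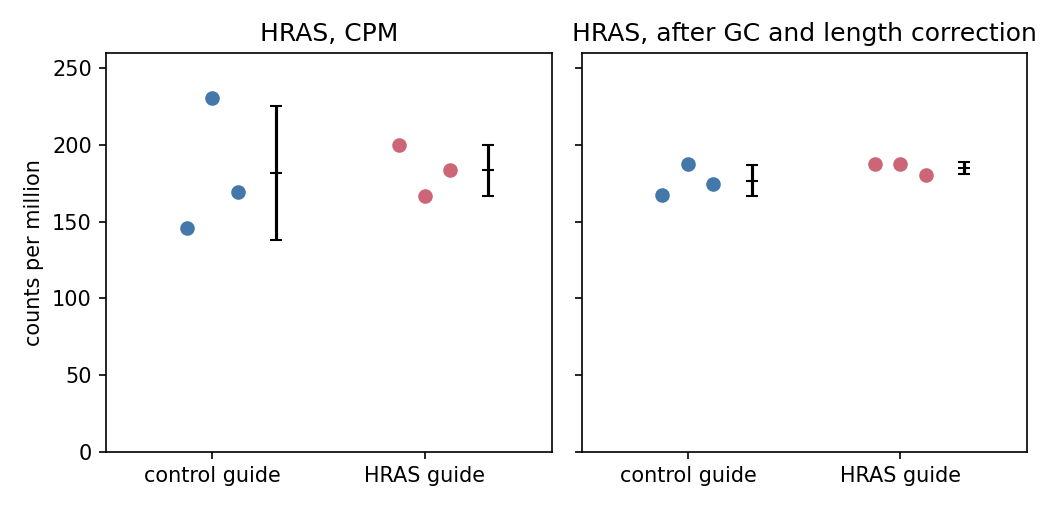
HRAS in CPM (vertical axis) in each library (points) by guide, with mean ± SD (black bars, n = 3), before (left) and after (right) removal of each library's GC content and length trend. The control libraries lie between 146 and 230 CPM before the correction and between 168 and 188 CPM after it.

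The libraries differed along GC content, in both groups. Spearman's rho across genes, which are not independent replicates, between GC content and a library's log2 CPM relative to the mean of all libraries was -0.46, 0.61 and -0.21 in control replicates 1 to 3. In HRAS guide replicates 1 to 3 it was 0.27, -0.49 and 0.06. HRAS transcripts have a GC content of 64.7%, within the highest decile of genes (62.1% or more). With the GC and length correction, chosen after seeing the data, HRAS stood at 177 ± 10.2 CPM with the control guide and 185 ± 4.05 CPM with the HRAS guide (SD, n = 3). The corrected log2 fold change was 0.07 ± 0.05 (SE), with a 95% interval of -0.05 to 0.18 and an adjusted p of 0.954. A covariate for sets of libraries that share the sign of the GC trend, also chosen after seeing the data, gave -0.09 ± 0.08 and an adjusted p of 0.648. Within the sets of negative and positive trend the uncorrected HRAS differences were 0.09 and -0.27. The sets share the sign of the trend but not its size. In the positive set control replicate 2 (0.61) stood against HRAS guide replicates 1 and 3 (0.27 and 0.06). This covariate can therefore leave part of the GC trend in HRAS.

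**Figure D2:**
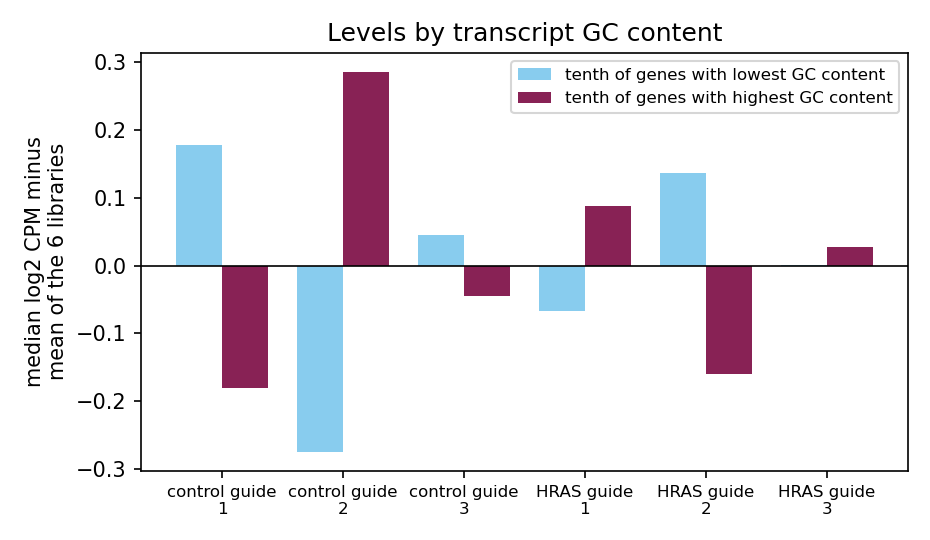
Median log2 CPM, relative to the mean of the 6 libraries (vertical axis), of the lowest and the highest decile of genes by transcript GC content, by library. Control replicate 2 stands at -0.27 and 0.29, and control replicate 1 at 0.18 and -0.18.

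With the HRAS guide, CAMK1G and HES1 fell, and immediate early genes fell as a group. CAMK1G, which encodes a calcium/calmodulin-dependent protein kinase, fell from 21.1 ± 1.24 to 5.63 ± 0.50 CPM (SD, n = 3), 0.268 of the control level. HES1, a transcriptional repressor of the Notch pathway, fell from 147 ± 12.2 to 84.8 ± 3.09 CPM (SD, n = 3). All 18 tested immediate early genes, which respond quickly to growth factors and stress, had negative log2 fold changes, with a median of -0.41.

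By edgeR, 2 of 19836 genes passed the threshold, 0 higher and 2 lower. The log2 fold change of CAMK1G (ENSG00000008118, GRCh38 chromosome 1, 209583717 to 209613938) was -1.90 ± 0.12, with an adjusted p of 0.000333. That of HES1 (ENSG00000114315, chromosome 3, 194136145 to 194138732) was -0.80 ± 0.09, with an adjusted p of 0.0486. All 3 HRAS guide libraries lay below all 3 control libraries for both genes, and chance gives such a separation, in either direction, to 10% of unchanged genes. At an unadjusted p under 0.05 there were 663 genes, 326 higher and 337 lower, where 992 would be called by chance. DESeq2 called 24 genes, 0 higher and 24 lower, which included both edgeR calls, and limma-voom called 1. The HES1 call ended without control replicate 3 (adjusted p = 0.333) and without HRAS guide replicates 1, 2 or 3 (0.367, 0.548 and 0.696), while its log2 fold change stayed between -0.84 and -0.72. CAMK1G passed in each of these fits. The number of genes called was 4 without control replicate 1, 24 without control replicate 2, and 1 without any of the other libraries.

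The other 8 of the 10 genes of smallest p were all lower with the HRAS guide but did not pass in edgeR. KRT87P, a keratin pseudogene whose reads can be shared with other keratin genes, had a log2 fold change of -0.86 ± 0.11 and BTBD19 one of -0.88 ± 0.12, both at an adjusted p of 0.0915. The transcription factor genes ATF3 (-0.66 ± 0.09), NR4A1 (-0.74 ± 0.11), JUN (-0.45 ± 0.07), EGR1 (-0.41 ± 0.06) and CSRNP1 (-0.82 ± 0.13) and the GTPase gene RHOB (-0.51 ± 0.07) had adjusted p between 0.0981 and 0.144. EGR1 stood at 1090 ± 9.50 CPM with the control guide and 822 ± 11.6 CPM with the HRAS guide, and JUN at 780 ± 8.64 and 573 ± 19.1 CPM (SD, n = 3). Exons of NR4A1 and of CSRNP1 overlap annotated genes on the opposite strand, so part of their counts is uncertain without strand. Each of these 8 genes passed in DESeq2 and after the GC and length correction.

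**Figure D3:**
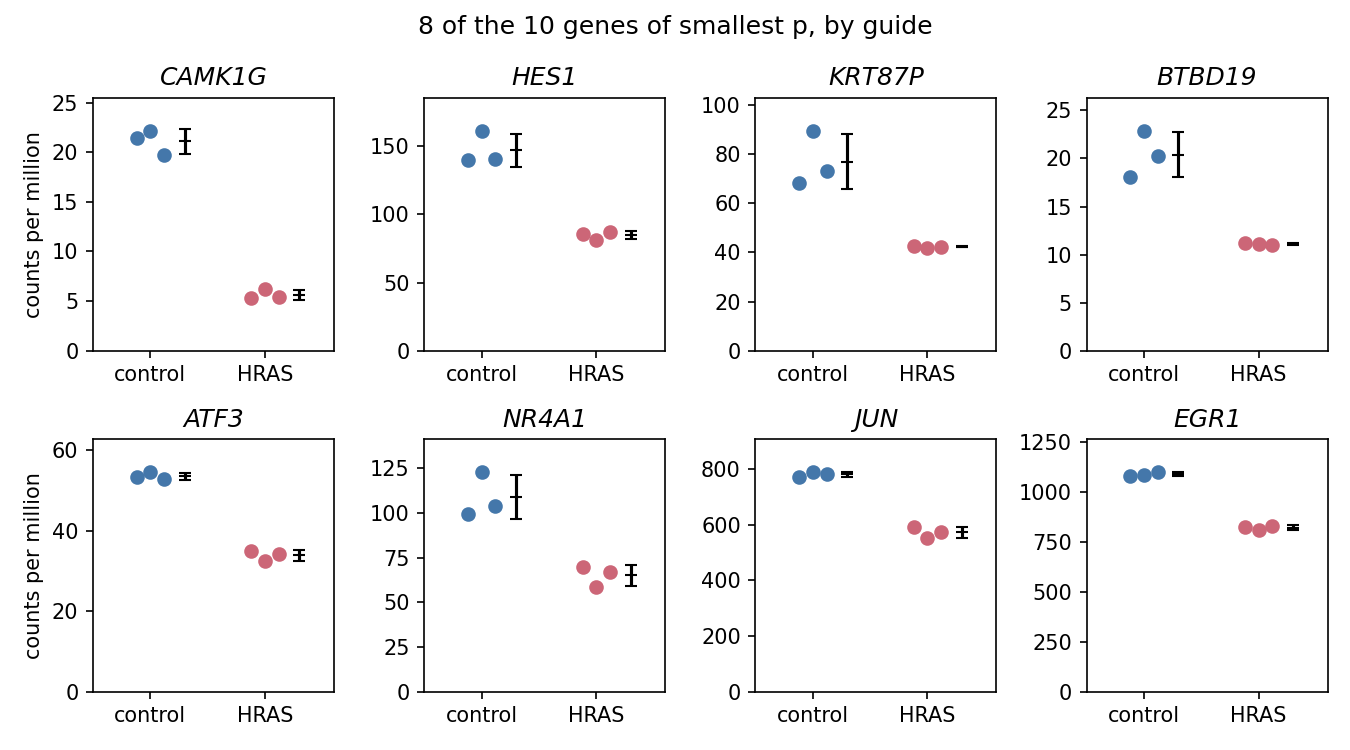
CPM (vertical axes, from 0) of 8 of the 10 genes of smallest p in each library (points) by guide, with mean ± SD (black bars, n = 3). In each of them the 3 HRAS guide libraries lie below the 3 control libraries, as for CAMK1G at 5.63 against 21.1 CPM. The genes were picked by their p in this same comparison, so the separation is no further support.

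After the GC and length correction, 39 of 19489 genes passed in edgeR, 2 higher and 37 lower, and both genes called without it were among them. Of these, 13 belonged to the immediate early, MAPK output, NF-kB or ER stress lists, and 21 were also called by DESeq2. Some lie close together, as CCDC85B (chromosome 11, 65890112 to 65891635) and FOSL1 (65892049 to 65900573). Others are DYNLT4 (chromosome 1, 44805913 to 44806675) and BTBD19 (44808482 to 44815585), and CAMK1G and LAMB3. Whether such neighbours are independent calls was not tested. The 4 lowest adjusted p after CAMK1G belonged to NR4A1 (-0.71 ± 0.05, adjusted p = 0.000312), HES1 (-0.80 ± 0.07), KRT87P (-0.81 ± 0.07) and, chosen after its values were seen, FOSL1 (-0.61 ± 0.05, adjusted p = 0.000675). The 2 higher genes, also chosen after their values were seen, were LUC7L3 (0.27 ± 0.04, adjusted p = 0.0473) and LENG8 (0.25 ± 0.04, adjusted p = 0.0488). Neither passed when GC content was corrected without length or as a straight line, which called 37 and 36 genes, all lower. Exons of both overlap other annotated genes. The corrected count was 37 without control replicate 1, 128 without control replicate 2, 8 without control replicate 3, and 7, 17 and 7 without HRAS guide replicates 1 to 3. The libraries also fell into sets by the sign of their GC trend, negative in control replicates 1 and 3 and HRAS guide replicate 2, and positive in the others. A fit with this set as a covariate called 81 genes, 11 higher and 70 lower, and kept both edgeR calls.

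The immediate early list fell as a group: 18 of 18 members were negative, 0 passed over all genes, and 14 were lower adjusted over the list alone (camera adjusted p = 1.07e-48, and adjusted p = 0.0179 with an estimated correlation). Besides ATF3 and JUN, these included EGR3 (-0.69 ± 0.12), FOSL1 (-0.64 ± 0.10) and DUSP5 (-0.53 ± 0.09), chosen after their values were seen. After the GC and length correction 8 members passed over all genes and 15 adjusted over the list alone. The median difference was -0.42 within the libraries of negative GC trend (2 control and 1 HRAS guide library) and -0.42 within those of positive trend (1 control and 2 HRAS guide libraries). After the correction these values were -0.40 and -0.28, with 18 and 16 of the 18 members negative.

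The MAPK output list, genes induced by ERK signalling, also fell as a group: 14 of 14 were negative, with a median of -0.20. None passed over all genes and 4 were lower adjusted over the list alone (camera adjusted p = 8.22e-09, and adjusted p = 0.0270 with an estimated correlation). HBEGF, an EGF receptor ligand (-0.54 ± 0.10), and EPHA2, a receptor tyrosine kinase (-0.39 ± 0.09), had the smallest p. After the correction 13 of 14 were negative, 3 members passed over all genes, 4 adjusted over the list alone, and the estimated correlation gave an adjusted p of 0.0518. Within the sets of negative and positive GC trend the median differences were -0.21 and -0.15, and -0.19 and -0.08 after the correction. With the library set as a covariate beside the correction the list median was -0.11. The RAS signalling components themselves were not called: 16 of 33 were positive and 17 negative, with a median of -0.0038 and a camera adjusted p of 0.429, and 0 passed either over all genes or adjusted over the list alone. KSR1 (-0.20 ± 0.11) and RRAS (-0.20 ± 0.14, and -0.30 to -0.03 with each library left out) had the smallest p in that list. Without HRAS its median was -0.0039.

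In the NF-kB and cytokines list, 19 of 23 members were negative, with a median of -0.12; 0 passed over all genes and 4 were lower adjusted over the list alone. The list fell as a group (camera adjusted p = 1.41e-08, and adjusted p = 0.0270 with an estimated correlation), led by the cytokine genes LIF (-0.51 ± 0.12) and CSF2 (-0.52 ± 0.13). Exons of LIF overlap antisense genes. After the correction 1 member passed over all genes and 8 adjusted over the list alone. The median differences within the sets of negative and positive GC trend were -0.12 and -0.15, and -0.11 and -0.08 after the correction. With the library set as a covariate the list median was -0.08.

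**Figure D4:**
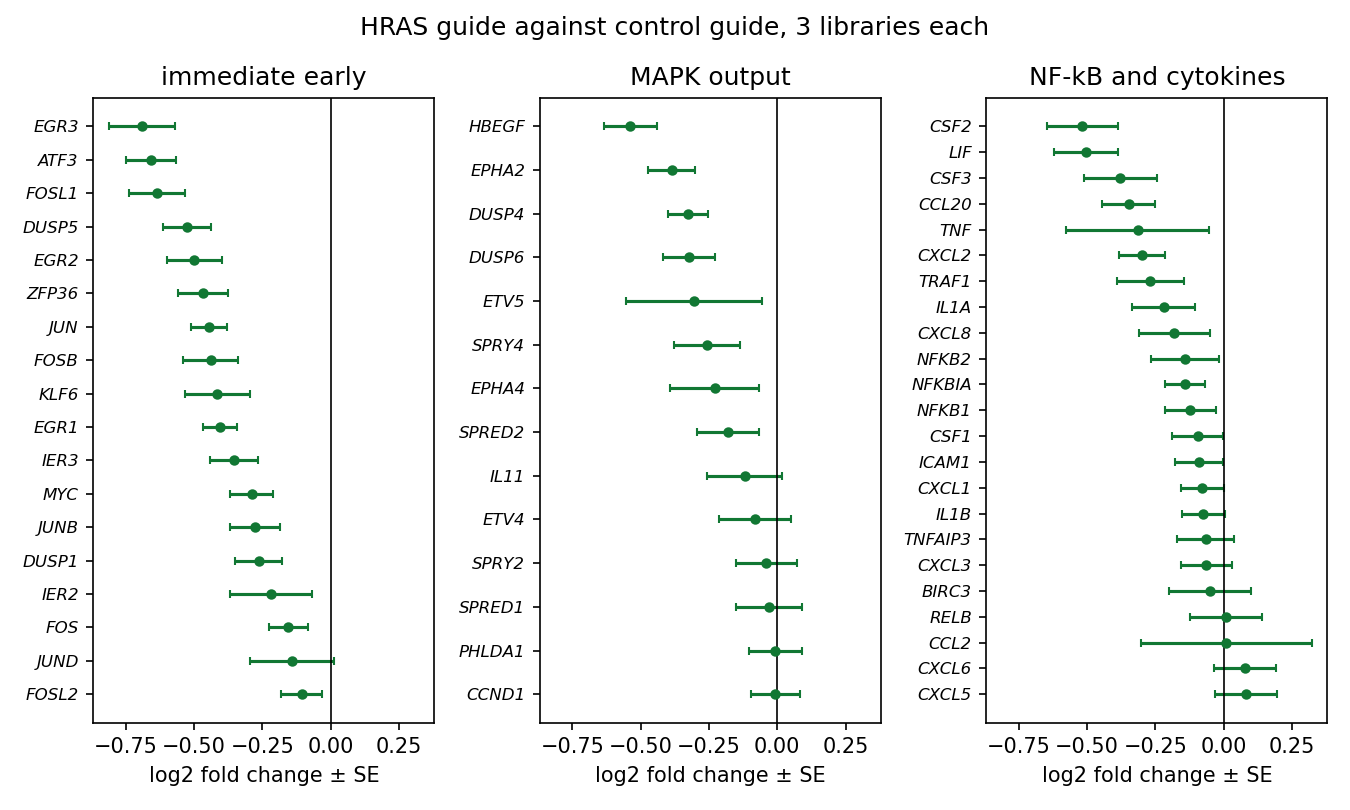
Log2 fold change, HRAS guide against control guide, with SE (horizontal axis), of each tested member of 3 lists fixed before the data were examined (18, 14 and 23 genes). All points of the immediate early and MAPK output lists lie below 0, as do 19 of 23 in the NF-kB and cytokines list.

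Without the correction, 6 further lists were called by camera at the preset correlation, but not with an estimated correlation or by fry, and in each of them 0 members passed over all genes. G2/M and mitosis genes were lower in 25 of 26 members, with a median of -0.09 and 0 members adjusted over the list alone (camera adjusted p = 0.000252, and adjusted p = 0.307 with an estimated correlation). NUSAP1 (-0.70 ± 0.22), at 1.87 CPM with the control guide, and KIF20A (-0.18 ± 0.10) had the smallest p, and both share exon sequence with overlapping genes. Within the libraries of positive GC trend 11 of the 26 were negative, with a median difference of 0.02, while within those of negative trend 25 were. After the correction 22 (median difference -0.09) and 25 (-0.12) were negative within these sets. In the corrected fit all 26 were negative, and the list was called with an estimated correlation (camera adjusted p = 0.0159) and by fry (0.00344). With the library set as a covariate and no correction the list was not called (median -0.05, camera adjusted p = 0.0877). Of 23 alternatives at the preset correlation, 22 kept its call. Without control replicate 2 the median was -0.19.

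FOXO targets were negative in 11 of 14 members, with a median of -0.06 and 1 lower adjusted over the list alone (adjusted p = 0.000512, and adjusted p = 0.291 with an estimated correlation), led by GADD45A (-0.38 ± 0.08) and SESN3 (-1.45 ± 0.46), the latter at 0.57 CPM with the control guide. With the library set as a covariate the list was not called (median -0.02, adjusted p = 0.0716). Its median was -0.03 without control replicate 1, -0.16 without control replicate 2 and -0.10 without HRAS guide replicate 2. Library totals alone gave -0.04, and the covariate with the correction -0.03. Interferon response genes were positive in 26 of 33 members, with a median of 0.09 and 0 adjusted over the list alone (adjusted p = 0.00474, and adjusted p = 0.263 with an estimated correlation). OASL (0.42 ± 0.11) and IFIT1 (0.37 ± 0.14) led this list, and its call ended without control replicate 2 (adjusted p = 0.109). The interferon median was 0.14 without control replicate 1 and 0.13 without HRAS guide replicate 1. After the correction fry called the list (adjusted p = 0.00344) and camera did not with an estimated correlation (adjusted p = 0.102 with an estimated correlation).

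Mesenchymal and invasion genes were negative in 17 of 22 members, with a median of -0.05 and 0 adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.268 with an estimated correlation). SNAI1 stood at -0.48 ± 0.22. The mesenchymal median was -0.14 without control replicate 2, -0.08 without HRAS guide replicate 2 and -0.03 with library totals alone. All 13 mitochondrial genome mRNAs were negative, with a median of -0.09 and 0 adjusted over the list alone (adjusted p = 0.0124, and adjusted p = 0.451 with an estimated correlation), as for MT-CYB (-0.12 ± 0.06) and MT-ND5 (-0.12 ± 0.07). Beside them, mitochondrial ribosomal RNAs took 1.39%, 1.34% and 1.41% of counts in the control libraries and 1.253%, 1.245% and 1.237% in the HRAS guide libraries. All 5 nuclear-retained and structured RNAs were positive, with a median of 0.09 (0.15 without control replicate 2) and 1 higher adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.261 with an estimated correlation), led by NEAT1 (0.29 ± 0.08) and GAS5 (0.15 ± 0.08). Calls of these 3 lists ended in several fits that left out a library: without control replicate 3 the adjusted p was 0.141 for each, and without HRAS guide replicate 3 it was 0.169, 0.169 and 0.126. The mesenchymal call also ended without control replicate 1 (0.174) and HRAS guide replicate 1 (0.0855), and the mitochondrial call without HRAS guide replicate 2 (0.0582). With the library set as a covariate the mesenchymal list had an adjusted p of 0.285. With the correction added to that covariate, the mesenchymal and the nuclear-retained lists were not called (0.0513 and 0.0858, the latter with a median of 0.05), and the mitochondrial median was -0.17.

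Without the correction, the RAS signalling list and the remaining lists were not called, and 0 of their members passed over all genes. Adjusted over the list alone, 0 members passed except 1 lower gene of the glycolysis and hypoxia list, VEGFA. DESeq2 called VEGFA too (adjusted p = 0.00106). After the GC and length correction, VEGFA (adjusted p = 0.00455) and PPP1R15A of the ER stress list (0.0112) passed over all genes in edgeR. Adjusted over the list alone, 3 heat shock genes were then lower, with 1 each in the p53, ER stress and glycolysis lists. Passes given below with a library left out or with the library set as a covariate come from camera at the preset correlation of 0.01 alone. Where the members of a list move together, such p-values can be far too small. The estimated correlation was 0.39 for the m6A machinery and 0.32 for YAP/TEAD targets. The m6A machinery had 15 of 20 members negative with a median of -0.02 (camera adjusted p = 0.285), and ALKBH5, the other m6A demethylase gene, stood at -0.14 ± 0.09; without control replicate 2 the list passed, lower, at an adjusted p of 0.00470. G1/S and DNA replication genes had a median of 0.01 (adjusted p = 0.824), with MCM6 at 0.10 ± 0.09 and CCNE1 at 0.09 ± 0.09. P53 targets and apoptosis genes had a median of -0.02 (adjusted p = 0.0996), with GDF15 at -0.48 ± 0.15 and CDKN1A at -0.20 ± 0.08; after the correction the list passed at 0.0369, but not with an estimated correlation (adjusted p = 0.230 with an estimated correlation) or by fry (0.159). ER stress and integrated stress genes had a median of -0.03 (adjusted p = 0.0889), with PPP1R15A at -0.37 ± 0.09 and DDIT3 at -0.32 ± 0.13; it passed without control replicate 1 (0.0469) and with the library set as a covariate (0.0393).

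Heat shock genes had a median of -0.07 (adjusted p = 0.0996), with DNAJB1 at -0.15 ± 0.08 and DNAJA1 at -0.13 ± 0.08; without control replicate 1 the list passed at an adjusted p of 0.0456, and after the correction at 0.00876, but not then with an estimated correlation (adjusted p = 0.370 with an estimated correlation) or by fry (0.249). Glycolysis and hypoxia genes had a median of -0.04 (adjusted p = 0.0996), with VEGFA at -0.49 ± 0.08 and ANKRD37 at -0.38 ± 0.19. This list passed, lower, without control replicate 1 (0.0301) and with the library set as a covariate (0.0476). YAP/TEAD targets had a median of -0.04 (adjusted p = 0.0996), with AMOTL2 at -0.28 ± 0.08 and AJUBA at 0.13 ± 0.07, and passed, lower, without control replicate 2 (0.00159) or HRAS guide replicate 2 (0.0334). Cholesterol synthesis genes had a median of -0.0038 (adjusted p = 1.00), with MSMO1 at 0.14 ± 0.09.

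Among the lists of cell identity, luminal urothelial genes had a median of -0.04 (camera adjusted p = 0.223), with ELF3 at -0.17 ± 0.10 and GATA3 at -0.13 ± 0.10. Basal and squamous genes had a median of 0.03 (adjusted p = 0.390), with SPRR3 at 0.49 ± 0.18 and KRT16 at -0.30 ± 0.15. KRT16 ran from -0.43 to -0.11 with each library left out. Markers of other cell types were also measured. CSF1R (-0.49 ± 0.20) and CD14 (0.34 ± 0.20), the 2 immune cell markers with enough counts, stood between 2.04 and 4.09 CPM. Fibroblast and muscle markers (adjusted p = 0.921) had PDGFRB at 0.53 ± 0.24 and THY1 at -0.11 ± 0.11, and passed, lower, without control replicate 1 (0.0427). Endothelial and red cell markers (adjusted p = 0.373) had CLDN5 at -0.51 ± 0.26 and VWF at -0.19 ± 0.18. HEK293 and neural markers (adjusted p = 0.217) had TUBB3 at -0.20 ± 0.15 and NEFL at -0.26 ± 0.22. HRAS chromosomal neighbours had a median of -0.02 (adjusted p = 0.429), with SCT at -0.72 ± 0.26 and CDHR5 at -0.16 ± 0.14. CDHR5 ran from -0.27 to -0.03 with each library left out. The list of neighbours passed in opposite directions without control replicate 1 (lower, 0.00148) and without control replicate 2 (higher, 0.00145). With the library set as a covariate it passed lower (0.000342). Its estimated correlation was 0.94, so these passes at the preset correlation cannot be read as shifts with the guide.

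Among housekeeping groups, cytosolic ribosomal protein genes had a median of 0.01 (camera adjusted p = 0.264), with RPS6 at 0.14 ± 0.09 and RPS23 at 0.09 ± 0.10. That list passed lower without control replicate 1 (0.0130) and with the library set as a covariate (0.0476), and higher without control replicate 2 (1.81e-10) or HRAS guide replicate 2 (0.0103). Its estimated correlation was 0.96, so these passes at the preset correlation cannot be read as shifts with the guide. Nuclear OXPHOS subunit genes had a median of 0.03 (adjusted p = 0.390), with NDUFA1 at 0.22 ± 0.14 and COX6C at 0.15 ± 0.10, and passed, higher, without control replicate 2 (1.61e-05). The same limit holds for that pass, as the estimated correlation of the OXPHOS list was 0.72. Replication-dependent histone genes had a median of -0.04 (adjusted p = 0.223), with H2BC8 at -0.35 ± 0.23 and H2BC5 at -0.22 ± 0.15.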

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

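The GC and length correction and the library set covariate were chosen after the results were seen. Of 20 alternatives for HRAS, 16 kept the sign and none passed the threshold; the sign turned with the library set covariate (-0.091), and leaving out each library gave -0.13 to 0.22. The 2 genes called by edgeR became 1 with DESeq2 size factors, with a filter of 1 CPM in 3 libraries, with limma-voom, with glmTreat and with a log2 fold change of at least 1, where CAMK1G remained; leaving out each library gave 1 to 24, the highest without control replicate 2. DESeq2 called 24 genes and edgeR without a filter 57, of which 4 were not tested otherwise. The GC and length correction called 39, GC content without length 37, a straight line 36, the library set covariate 81, and both together 82. The corrected count ran from 7 to 128 with each library left out. The cause of these differences was not tested.

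With the replicate block 1 gene was called, and with block and correction 5; the block left 6 lists called by camera, without the mesenchymal, mitochondrial mRNA and nuclear-retained lists. The counts gave no sign that the numbers pair the libraries. Same-number deviations from the group means correlated at -0.19, -0.30 and -0.06 across genes, and no library correlated best with its own number. After the correction the values were -0.09, -0.14 and -0.04. The GC trends shape these correlations, so a smaller effect shared by libraries of the same number cannot be excluded. Of 27 lists, 9 were called by camera, 3 with an estimated correlation, 3 by fry, and 6 to 14 with each library left out. After the correction 11 were called, 3 with an estimated correlation, 5 by fry, and 9 to 15 with each library left out. The immediate early, MAPK output and NF-kB lists were called lower by camera at the preset correlation in all 23 alternatives run for them. After the correction, the 3 lists called with an estimated correlation were immediate early, NF-kB and G2/M. MAPK output was not called there (camera adjusted p = 0.0518).

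Signs also turned for genes near 0. NRAS stood at 0.036 with the library set covariate and at -0.23 to 0.021 with each library left out. With correction and covariate together RPS6 stood at -0.012, RPS23 at -0.049 and COX6C at -0.0014. Depth limits the low genes, such as SESN3 at 0.57 CPM.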

Other observations

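Of the tests in this part, those of the splits of the libraries, of control replicate 2 alone, of heat shock genes and of the CAMK1G paralogs were written before their results were seen, and the other tests only afterwards, as was the margin for the spread of list members used on list medians. Genes outside the lists also passed with the HRAS guide after the GC and length correction, all chosen after their values were seen. The library set covariate and the correction together called 82 genes, 12 higher and 70 lower, and included all 39 genes of the corrected fit. That covariate was read from the same counts, so this is no independent support. With the correction alone, lower genes included KLF10 (-0.53 ± 0.05) and MAFF (-0.36 ± 0.06), which encode growth factor-responsive transcription factors. TNS4 (-0.37 ± 0.04) and LAMB3 (-0.28 ± 0.04), genes of cell adhesion, and SEMA7A (-0.31 ± 0.05) were lower as well. None of these lower genes passed in edgeR without the correction, and DESeq2 called only KLF10 among them (adjusted p = 0.0188). The higher gene LUC7L3 (0.27 ± 0.04) encodes a splicing factor, but did not pass when GC content was corrected without length, which called 37 genes.

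HRAS varied more among the control libraries than among the HRAS guide libraries, and GC content of the transcripts is a candidate explanation. Removal of each library's GC and length trend brought the SD of HRAS log2 CPM over the 3 control libraries to 0.245 of its value before. Control replicates 2 and 1, with the highest and lowest HRAS of the controls (230 and 146 CPM), had totals of 28374402 and 28657817 counts. The log2 ratio of these totals, taken without its sign, was 0.0217 of that of HRAS CPM. CPM are already scaled by library size and this test was written afterwards, so the share shows only that the depths were close. The GC trend was found in these data, so this remains a hypothesis. No biological explanation was tested, and HRAS protein and m6A were not analysed here.

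The immediate early genes were lower in the libraries with the HRAS guide. A GC content or length trend as the whole cause is argued against by the median after the correction, -0.39, though within the libraries of positive GC trend it was then -0.28, and control replicate 2 as the sole source by the median without it, -0.37. A stress response that differed between groups cannot be told apart, and its test used heat shock genes alone. The heat shock median, -0.071, lies on the side of its bound that argues against it, but within the margin added afterwards. After the correction the heat shock list passed by camera at the preset correlation (adjusted p = 0.00876). It did not pass then with an estimated correlation (adjusted p = 0.370 with an estimated correlation) or by fry (0.249). Adjusted over the list alone, 3 of the 12 heat shock genes were lower after the correction. The ER stress list, outside this test, had 14 of 20 members negative, with a median of -0.03 (camera adjusted p = 0.0889). After the correction 11 of its 20 members were negative, and 1, PPP1R15A, passed over all genes, lower. Lower RAS-MAPK output at the HRAS guide is a possibility that these values cannot decide. The MAPK output median was -0.20, but this test was written after that value was seen. No test here told it apart from a stress or handling difference, and the NF-kB list fell too (median -0.12). HRAS mRNA did not differ detectably. After the correction, camera with an estimated correlation gave the MAPK output list an adjusted p of 0.0518. A difference in handling between the groups stays open as well, since the labels give 48 h for all libraries but no batch or day.

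CAMK1G fell most among the genes called by edgeR, and reads from a neighbour or from paralogs were weighed as causes. CAMK1G ends 931 bases before the convergent gene LAMB3 (chromosome 1, 209614870 to 209652466, minus strand). LAMB3 was lower too, at -0.32 ± 0.09 in edgeR, where it did not pass. After the GC and length correction it stood at -0.28 ± 0.04 and passed (edgeR adjusted p = 0.0276). The log2 fold change of CAMK1G minus that of LAMB3 was -1.58, beyond 2 SE of 0.15, with both genes taken as independent. This argues against a constant share of LAMB3 reads as the whole cause. A share that changed between the groups was not tested. The paralogs CAMK1, CAMK1D and PNCK together changed by -0.085 CPM for each CPM that CAMK1G lost, so they did not gain its reads. An effect of the HRAS guide on CAMK1G itself stays open, as the guide sequence was not analysed here.

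There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The guides gave 2 genes in edgeR, and the highest other split 2018; 2 splits, the guides included, gave at least as many as the guides. After the GC and length correction the guides gave 39 genes and the highest other split 402, again with 2 splits at or above the guides. In both cases the other split parted control replicates 1 and 3 and HRAS guide replicate 2 from the rest, the libraries of negative from those of positive GC trend. It points to a structure among the libraries that is not the guide and that the correction removed only in part. With this split as a covariate the guides gave 81 genes, and 82 with the correction added.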
